A study of Homo sapiens with 6 samples.

How the data were processed

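Expression was measured by sequencing total RNA from 6 cultures of human lung adenocarcinoma lines, 1 library per line, after depletion of ribosomal RNA with a stranded TruSeq Ribo-Zero kit. The 2 parental lines were PC-9 and HCC827, which carry activating EGFR mutations and are sensitive to EGFR tyrosine kinase inhibitors. Each had 2 derived resistant lines, given in the labels as PC-9GR, PC-9ER, HCC827GR and HCC827ER, and 1 label reads HCC82GR, taken here as HCC827GR. The labels do not spell out GR and ER. All lines were grown in RPMI medium with serum.

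The values in the deposited tables are expected counts per gene, which are estimates from an upstream counter and not always whole numbers. The submitters' notes name alignment with HISAT2 2.0.4 to GRCh38.p13 and testing with Cuffdiff, and the program that made the expected counts is not given in the sources used here. Of the values per library, 13.2% (HCC827ER) to 14.3% (PC-9ER) were not whole, and all were rounded before testing. The libraries came in 2 tables. The first held PC-9, PC-9GR, HCC827 and HCC827GR with 16843 genes, and the second held PC-9ER and HCC827ER with 16304 genes. The 15998 genes listed in both were used, and 845 genes of the first table and 306 of the second were left out of the comparisons. No gene of the first table was at 0 in its 4 libraries, whereas 399 genes of the second were at 0 in both of its libraries. Both ER lines, and no other library, are in the second table, so a difference of the tables cannot be separated from ER against GR or from ER against the parental lines. XIST and Y-linked genes, 11 in all, were left out.

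Total counts were 16897444 for PC-9, 17855049 for PC-9GR, 17244870 for PC-9ER, 14529322 for HCC827, 14975504 for HCC827GR and 17292305 for HCC827ER. A count of 0 allows up to 3 counts, or 0.168 (PC-9GR and PC-9ER), 0.172 (PC-9), 0.185 (HCC827GR), 0.198 (HCC827) and 0.211 (HCC827ER) CPM, which are counts scaled to 1000000 per library. Reads carry no molecular identifiers, so intervals, which are at 95%, and floors cover counting error only.

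Tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter (13492 genes tested), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. The 5 comparisons were resistant against parental lines with line of origin as a block, the derived lines of PC-9 against PC-9, those of HCC827 against HCC827, the difference between these changes, and ER against GR lines with line of origin as a block. No line has a second library, so the spread is that between derived lines. A p value thus says nothing of repeat cultures of a line. Each test takes 1 spread per gene from the lines of both parents, with 3 residual degrees of freedom in the first comparison and 2 in the others. A log2 fold change is given ± its standard error from the fit. Single pairs, 1 derived against 1 parental library, have no test: a gene counted as changed in size when its log2 ratio of CPM, with a prior count of 2, was at least 1 either way and 1 library had at least 1 CPM. The 4 pairs use 2 parental libraries, so pairs of a parent share its noise. Their correlation, covariance and shared genes were set beside 20 simulated draws of unchanged derived lines with an assumed dispersion of 0.05 and, chosen after the data had been seen, with the 0.416 estimated between derived lines. The agreement of all 4 pairs was set beside independent lists and 10000 shuffles of gene identity between the parents.

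The 31 gene lists were trefoil factors and mucins, Hippo pathway components, YAP and TAZ targets, the ERBB family, bypass receptors, MAPK output, epithelial genes, mesenchymal genes, alveolar and airway genes, squamous and basal genes, neuroendocrine markers, proliferation genes, interferon-stimulated genes, NF-kB and inflammation genes, antigen presentation, apoptosis regulators, drug handling, NRF2 targets, glycolysis and hypoxia, TGF-beta targets, Notch and Wnt genes, integrated stress and unfolded protein genes, sterol and lipid synthesis, integrins and matrix, cancer-testis antigens, leukocyte markers, endothelial markers, fibroblast markers, replication-dependent histone mRNAs, mitochondrial mRNAs and small structural RNAs. The 28 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry. Several symbols stand in more than 1 list.

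The named genes follow a rule. TFF3, YAP1, WWTR1, EGFR and MET were named in every comparison. In resistant against parental lines, the rule took the 10 highest and 10 lowest fold changes among genes past the threshold with 1 direction in all 4 pairs, and, where fewer than 5 passed, the genes with the largest smallest log2 ratio over the pairs, said to be named by size only. Within each parent it took 8 each way, for the difference and for ER against GR 5 each way, and in each single pair 3 each way with at least 10 CPM in the higher library. Genes needed at least 5 CPM in 1 library, and clone or locus symbols were left out. Up to 4 members were named for each list described. Some genes the rule took are not used here. The comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined. Chosen afterwards were the list tests for ER against GR, which lists have members named, medians with counts under 3 raised to 3, leave-one-out for the lists and the pair agreement, fits of the first table alone, genes absent from 1 table set to 0, fits without the library labelled PC-9GR, and the work on chromosome regions.

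Alternatives, changed 1 at a time, were the size factors of DESeq2 in edgeR, no low-count filter, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no block for line of origin, each library left out in turn, a prior count of 0.5, a minimum of 5 CPM and a 4-fold threshold. Without PC-9 or HCC827, resistant against parental lines gives the change in the other parent's lines alone. The pipeline was tested on simulated data. At the spread estimated here (dispersion 0.416), resistant against parental lines found 0% of genes with planted 2-fold changes, 4% of 4-fold, 24% of 8-fold and 62% of 16-fold changes. At a dispersion of 0.05 it found 48% of 2-fold and 100% of larger ones. With a dispersion of 0.416, 12% of 16-fold changes were found within 1 parent, 0% in the difference, and 0% in ER against GR. At 0.05 each of these found 100% of 16-fold changes. A list planted at 2-fold with a dispersion of 0.416 was called by camera in the first comparison (adjusted p = 0.00126), not in the difference (adjusted p = 0.992). With an estimated correlation it was not called in the first comparison (adjusted p = 0.578). At 0.05 camera called it in the first comparison and in the difference (adjusted p = 3.68e-07). With an estimated correlation it was then called in the first (0.0237) and not in the difference (0.696). No other list was called, but the simulated genes varied independently, so this does not test lists whose genes move together.

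Gene positions are from GENCODE v29 on GRCh38 and matched 15700 of the 15998 genes. For regions, the median log2 ratio was taken in windows of 9 neighbouring genes with at least 5 CPM in 1 library (12113 genes), against a threshold of 1.5 and 100 shuffles of gene order. A gene was called silent at 3 counts or fewer and expressed at 5 CPM or more.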

Results

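RNA was sequenced from 6 lung adenocarcinoma lines with 1 library each, so no line has a replicate. PC-9 and HCC827 were the parental lines, and each had a GR and an ER derivative with acquired resistance to EGFR tyrosine kinase inhibitors. The series design text describes 4 pairs of parental and resistant lines and asks which signalling pathways are responsible for the resistance. Its title names TFF3, a secreted trefoil peptide, and the Hippo pathway, which restrains the transcriptional coactivators YAP1 and WWTR1 (TAZ). Total counts ranged from 14529322 in HCC827 to 17855049 in the library labelled PC-9GR, and 14754 to 15085 genes were detected per library. Expression is given in CPM, counts scaled to 1000000 per library, for PC-9, PC-9GR, PC-9ER, HCC827, HCC827GR and HCC827ER, in this order where 6 values follow each other.

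PC-9ER, HCC827GR and HCC827ER resembled their parental lines, with Spearman correlations across genes of 0.96, 0.942 and 0.888. The library labelled PC-9GR did not: its correlation was 0.773 with PC-9, 0.828 with HCC827GR and 0.821 with HCC827, whereas PC-9 and HCC827 correlated at 0.831. In it, 323 genes silent in PC-9 were expressed and 254 genes expressed in PC-9 were silent, against at most 36 and 43 in the other pairs. LCP1, an actin-bundling protein, was at 918 CPM in PC-9, ANO1, a chloride channel, at 804, and MAL, a membrane raft protein, at 724, and each had at most 3 counts in this library. CDKN2A, which encodes the cell cycle inhibitor p16, went from 201 CPM in PC-9 to 0 counts, and SMARCA4, a chromatin remodelling ATPase, from 346 to 9.50 CPM. Genes are not independent replicates, and the list tests are also given without this library. Values of its single pair rest on it alone. HCC827ER had 16.1% of its counts in ribosomal protein genes, against 5.81% to 8.47% in the other libraries.

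**Figure D1:**
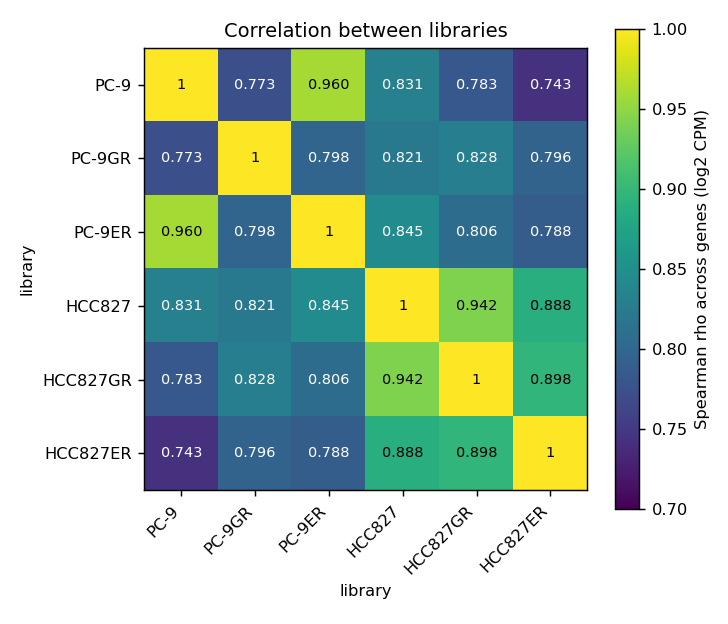
Spearman correlation across genes of log2 CPM between each pair of the 6 libraries, as numbers and colours from dark (low) to light (high). The library labelled PC-9GR reaches 0.773 with PC-9, while PC-9ER reaches 0.96.

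TFF3 (chromosome 21, 42311667 to 42315651, GRCh38) was close to absent: the first table held 0 counts in PC-9, HCC827 and HCC827GR and 1 count in the library labelled PC-9GR, and the second table did not list it. A count of 0 allows up to 0.172 CPM in PC-9 and 0.198 CPM in HCC827, so a fall of TFF3 could not be seen at this depth. No rise beyond 1 count was seen in the GR lines. Its level in the ER lines is not known, since no value is listed for them. The related TFF1 had 20 counts in PC-9, 3 in PC-9GR and in PC-9ER, and 0 in the 3 HCC827 libraries, and TFF2 had 9, 0 and 2 counts in the PC-9 libraries and 0 in the others.

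EGFR (NCBI gene 1956, chromosome 7, 55019021 to 55211628), the receptor these inhibitors target, was lower in all 4 resistant lines: 1181, 347, 464, 5213, 585 and 1300 CPM, a log2 fold change of -2.03 ± 0.48. YAP1 (10413, chromosome 11, 102110461 to 102233423) was also lower in all 4 pairs, at 198, 69.3, 102, 113, 100.3 and 48.5 CPM (-0.92 ± 0.42), though by only -0.17 in HCC827GR. WWTR1 (25937, chromosome 3, 149517235 to 149736714) had no common direction, at 98.3, 226, 47.0, 217, 214 and 123 CPM (0.04 ± 0.68). MET (4233, chromosome 7, 116672390 to 116798386), a receptor kinase that can bypass EGFR, was higher in PC-9GR and lower in the other 3, with 158, 242, 151, 590, 430 and 115 CPM (-0.46 ± 0.65). None of these 4 genes passed the test (adjusted p = 0.999 each, edgeR), and the fitted direction of WWTR1 and MET depended on the libraries used. Without PC-9GR WWTR1 was at -0.68. Without HCC827, which leaves the change in PC-9 alone, MET was at 0.31.

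**Figure D2:**
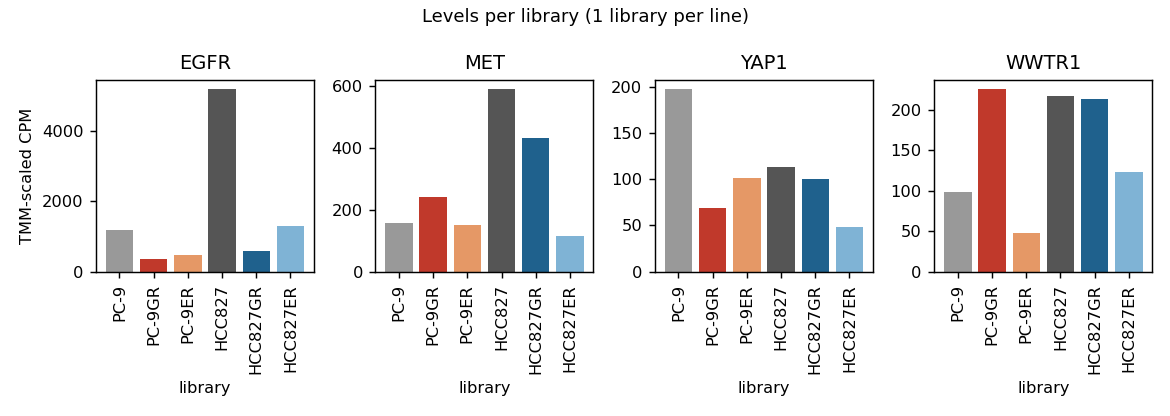
Bars give the TMM-scaled CPM, on a linear axis from 0, of EGFR, MET, YAP1 and WWTR1 in the 6 libraries, 1 bar per library without error bars, since no line has a replicate. EGFR lies at 347 to 1300 CPM in the 4 resistant lines and at 1181 and 5213 CPM in their parents.

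In all 4 pairs the resistant line had more transcripts of the aldo-keto reductase AKR1C2 and of the mesenchymal filament vimentin, and fewer of the ERK feedback regulators DUSP6 and SPRY4 and of TMPRSS4, than its parent, and none of these 5 genes passed the test adjusted over all genes. AKR1C2 (1646, chromosome 10, 4987400 to 5018031), which reduces steroids and reactive carbonyls, was at 63.9, 4742, 2489, 0.724, 32.9 and 520 CPM (log2 fold change 6.90 ± 1.66). VIM (7431, chromosome 10, 17228259 to 17237593), vimentin, was at 5.09, 1386, 163, 93.7, 860 and 878 CPM (4.72 ± 1.52). DUSP6 (1848, chromosome 12, 89347232 to 89353271), the phosphatase that switches off ERK, was at 90.7, 11.1, 7.05, 15.2, 1.42 and 0.421 CPM (-3.67 ± 0.56), and SPRY4, a feedback inhibitor of receptor kinase signalling, at 84.8, 11.5, 1.18, 17.2, 2.10 and 1.12 CPM (-3.58 ± 0.84). The membrane serine protease TMPRSS4 (56649, chromosome 11, 118077012 to 118121890) was at 19.9 and 4.08 CPM in the parents and at 0 to 0.224 CPM in the resistant lines.

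The other genes named by size only had fitted log2 fold changes of 3.02 to 9.78 (higher) or -5.63 to -3.25 (lower). Among the higher ones were the endocytic receptor relative LRP3 (0.0572, 121, 4.93, 0, 3.40 and 1.19 CPM), the RAS relative MRAS (1.72, 19.6, 7.33, 0, 8.53 and 7.93 CPM), the phospholipase PLA2G4C (3.69 ± 0.90), GAREM2, an adaptor of growth factor receptors (4.09 ± 1.46), the axon guidance protein NTNG2, the gamma-secretase subunit APH1B (3.02 ± 1.14) and the methionine sulfoxide reductase MSRB3 (3.18 ± 1.42). The lower ones were the gastrointestinal calpain CAPN8, the membrane mucin MUC20 (16.9, 1.29, 1.90, 8.89, 0.247 and 1.47 CPM), the cadherin relative PCDH1 (-4.08 ± 1.35), the placental phosphatase ALPP (-3.66 ± 1.24), the surface protein LY6D (-3.25 ± 1.60), the potassium channel KCNJ18 and tyrosine hydroxylase, TH. Fitted folds of genes at 0 or with up to 3 counts in some libraries, such as LRP3, TMPRSS4 and TH, depend on the prior count and are no bounds. Reads of AKR1C2, ALPP and KCNJ18 can come from close paralogs.

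No single gene passed the edgeR test of resistant vs parental in both lines (smallest adjusted p = 0.999). At an unadjusted threshold of 0.05 there were 342 genes, 171 each way, where 675 would be expected by chance, DESeq2 called 21 higher and 13 lower, EGFR among them (adjusted p = 0.0343), and limma-voom called 0 with 490 at the unadjusted threshold. The simulated data had 62% of 16-fold and 24% of 8-fold changes called at this spread, so a missing call does not show that a gene was unchanged.

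**Figure D3:**
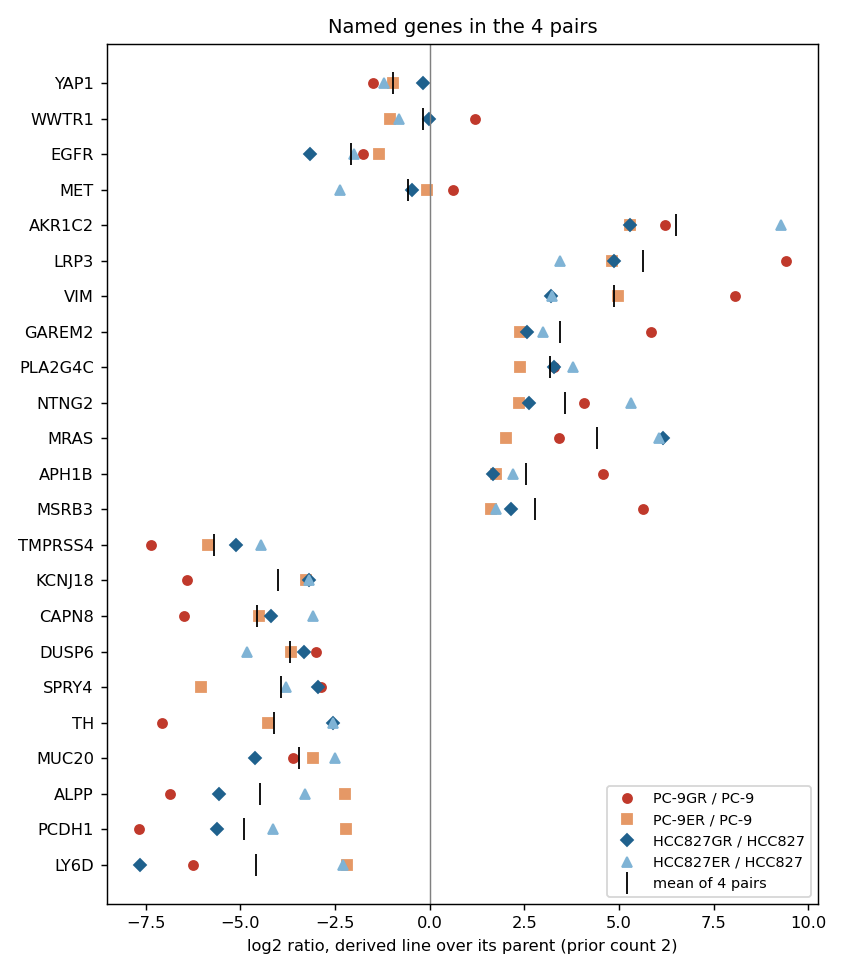
Log2 ratio of each derived line to its parent (prior count of 2) for the fixed genes and the genes named in the text by size over both parents, 1 point per pair, with a black tick at the mean of the 4 pairs. AKR1C2 lies between 5.28 and 9.27 and DUSP6 between -4.82 and -3.01.

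MAPK output genes, transcripts driven by ERK, fell as a list (adjusted p = 2.81e-11, limma camera), a call lost with an estimated correlation (adjusted p = 0.409) and with fry (adjusted p = 0.303). All 22 tested members were lower in the fit and 15 were lower in every pair, with medians of -1.04, -2.15, -0.99 and -1.18 in PC-9GR, PC-9ER, HCC827GR and HCC827ER (-1.05, -2.21, -1.0 and -1.19 with counts under 3 raised to 3). DUSP1, a related phosphatase outside the list, was at least 2-fold higher in all 4 pairs. Adjusted over the list alone, 3 genes passed, DUSP6 (adjusted p = 0.0130) and SPRY4 and DUSP5 (-1.76 ± 0.40, adjusted p = 0.0388 each), and EGR1, an immediate early transcription factor, was lower in every pair (-2.95 ± 1.24). The ERBB family also fell (adjusted p = 0.0102, and 0.409 with an estimated correlation), with 11 of 14 members lower and medians of -0.49, -0.53, -1.28 and -1.28 (-1.41 for HCC827ER at the floor). The call was lost without HCC827, where the fit gives the change in PC-9 alone. The EGFR ligands EGF (-2.08 ± 0.79) and TGFA (-1.64 ± 0.63) were lower in all 4 pairs, and LRIG1, a protein that promotes EGFR turnover, was higher in all 4 (1.82 ± 0.94).

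Epithelial identity genes fell as a list (adjusted p = 2.81e-11; adjusted p = 0.498 with an estimated correlation). All 30 tested members were lower in the fit and 18 were lower in every pair, but the size differed between lines, with medians of -5.93 in the library labelled PC-9GR, -0.42 in PC-9ER, -3.08 in HCC827GR and -1.65 in HCC827ER (-6.01, -0.42, -3.10 and -1.65 at the floor). GRHL2, a transcription factor that maintains epithelium, was at 91.2, 0, 98.4, 55.3, 0.185 and 3.16 CPM, and the epithelial splicing factor ESRP1 at 256, 0.224, 202, 224, 1.30 and 17.3 CPM. The mesenchymal list rose (adjusted p = 0.00932; adjusted p = 0.409 with an estimated correlation), with 16 of 26 members higher and medians of 1.47, 0.58, 0.13 and 0.19 (1.47, 0.59, 0.09 and 0.20 at the floor). ZEB2, a repressor of E-cadherin, was higher in every pair (3.15 ± 1.13), and ZEB1 was at 0.630, 25.2, 0.728, 6.12, 34.1 and 9.90 CPM. Without PC-9, where the fit gives the change in HCC827 alone, the mesenchymal call was lost.

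Sterol and lipid synthesis fell (adjusted p = 1.13e-05; adjusted p = 0.498 with an estimated correlation), with 27 of 32 members lower and medians of -0.39, -1.01, -0.75 and -0.17. HMGCS1, an early enzyme of cholesterol synthesis (-1.46 ± 0.34), was lower in all 4 pairs. NRF2 targets, the genes of the oxidative stress response, rose (adjusted p = 2.04e-05; adjusted p = 0.552 with an estimated correlation), with 24 of 28 higher, 9 of them in every pair, and medians of 1.84, 0.29, 0.17 and 0.66. HMOX1, heme oxygenase, was at 30.3, 278, 62.4, 20.8, 160 and 112 CPM (2.60 ± 0.70). The NRF2 call was lost without PC-9, where the fit gives the change in HCC827 alone.

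The list of trefoil factors and mucins fell (adjusted p = 0.00112, and 0.409 with an estimated correlation), with 8 of 13 tested members lower, 7 of them in every pair, and medians of -1.89, -1.24, -4.29 and -1.61 (-1.90, -1.24, -4.34 and -1.62 at the floor). No trefoil factor was among the tested members, here or in the other comparisons. TFF1 and TFF2 had too few counts, and TFF3 was not listed for the ER lines. Of the lower members, the airway mucin MUC5B was at 29.6, 1.01, 0.0560, 26.3, 0.247 and 8.57 CPM, the surface mucin MUC16 at 354, 0, 122, 219, 5.87 and 11.2 CPM, and SPDEF, a goblet cell factor, at 53.7, 14.4, 4.54, 4.74, 0 and 0.421 CPM. Integrins and matrix fell (adjusted p = 0.000683, and 0.409 with an estimated correlation), with 22 of 32 lower and medians of -1.31, -0.47, -0.23 and -0.61 (-0.65 for HCC827ER at the floor). This call was lost without PC-9, where the fit gives the change in HCC827 alone. ITGA2, a collagen receptor subunit, was at 539, 71.5, 93.5, 38.2, 10.0 and 4.07 CPM (-2.57 ± 0.43) and passed adjusted over the list alone (adjusted p = 0.0304). Over both parents, 4 list members passed adjusted over the list alone.

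Neither Hippo list passed. Of 30 Hippo pathway components 19 were lower (median -0.25; adjusted p = 0.104, and 0.0382 without HCC827GR), among them the upstream kinase MAP4K4 (-1.01 ± 0.48), while the DNA-binding partner TEAD2 was higher in 3 pairs and lower in HCC827GR (-0.55; 1.12 ± 0.70 in the fit). Of 22 YAP and TAZ targets 11 were higher and 11 lower (adjusted p = 0.873), with a median of 0.10, a mean of -0.07 and a test direction of higher. Its members did not move as 1 block: the receptor kinase AXL was higher in every pair (68.5, 130, 253, 24.2, 138 and 67.8 CPM, 1.78 ± 0.51), and NT5E, which makes adenosine outside the cell, was lower in every pair (-2.69 ± 0.83).

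**Figure D4:**
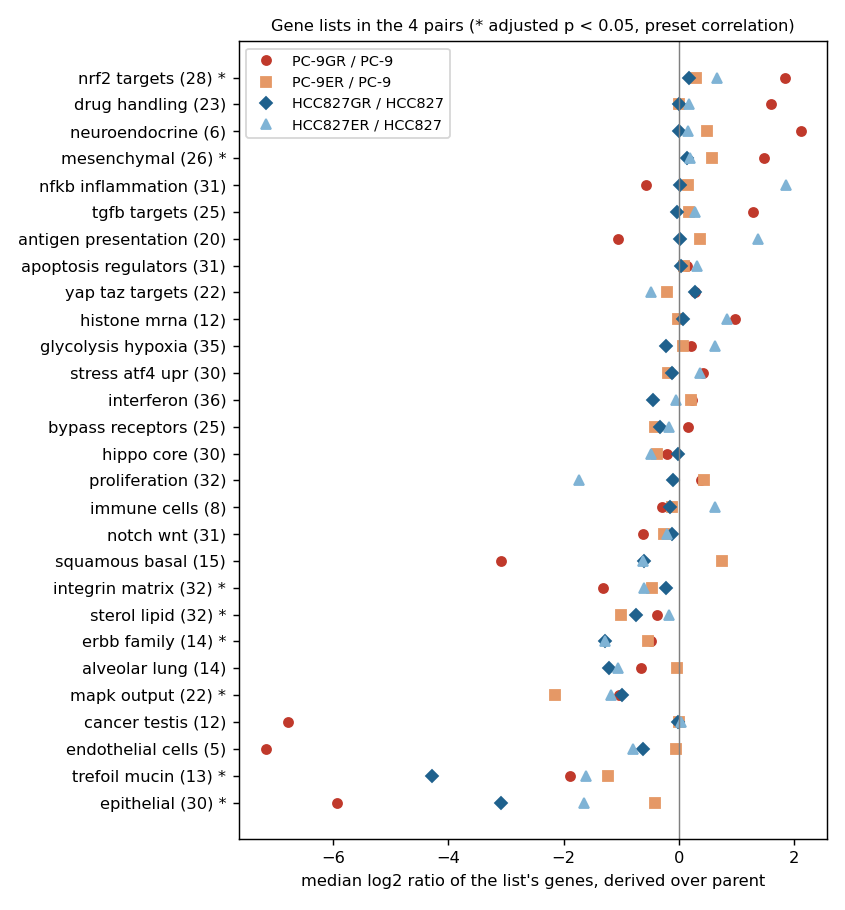
Median log2 ratio of each tested gene list in each derived line against its parent, 1 point per pair, with the number of tested members in brackets and an asterisk for an adjusted p under 0.05 at the preset correlation. The MAPK output list lies between -2.15 and -0.99 in all 4 pairs, while the epithelial list ranges from -5.93 to -0.42.

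In the remaining lists no change was called over both parents. Higher were 16 of 23 drug handling genes (adjusted p = 0.0976), 22 of 31 NF-kB and inflammation genes (0.0976), 8 of 12 histone mRNAs (0.125), 16 of 25 TGF-beta targets (0.198), 18 of 31 apoptosis regulators (0.262), 5 of 6 neuroendocrine markers (0.281), 13 of 20 antigen presentation genes (0.397), 20 of 35 glycolysis and hypoxia genes (0.592) and 17 of 30 stress response genes (0.847). Lower were 11 of 14 alveolar and airway genes (0.0883), 20 of 31 Notch and Wnt genes (0.0976), 11 of 15 squamous and basal genes (0.0976), 4 of 5 endothelial markers (0.0976), 25 of 32 proliferation genes (0.198), 16 of 25 bypass receptors (0.592), 8 of 12 cancer-testis antigens (0.616), 22 of 36 interferon-stimulated genes (0.847; median -0.12, mean 0.0011) and 5 of 8 leukocyte markers (0.873). Among the bypass receptors, FGFR1 was higher in every pair (12.3, 153, 31.5, 35.2, 256 and 166 CPM, 2.75 ± 0.75) and MST1R, the receptor kinase RON, lower in every pair (-1.96 ± 0.61). Fibroblast markers, mitochondrial mRNAs and small structural RNAs were not tested, with 3, 0 and 0 tested members.

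Without the library labelled PC-9GR all 8 calls over both parents held, and NF-kB and inflammation genes (higher, adjusted p = 0.00260), alveolar and airway genes (lower, 0.0263) and antigen presentation (higher, 0.0393) were called as well, but none of these 11 lists with an estimated correlation (smallest adjusted p = 0.517). Other libraries decided calls at the preset correlation too. Without PC-9 or HCC827, though, the fitted change is that of the other parent's derived lines alone, not of both parents. NF-kB genes were called without PC-9 (0.000740) and without HCC827GR (0.0234), alveolar genes without PC-9 (0.0320), and squamous and basal genes without PC-9 (0.0353) and without PC-9ER (0.00806). Drug handling (0.0330) and TGF-beta targets (0.0424) were called without PC-9ER. Proliferation genes were called lower without PC-9 (1.27e-06) or HCC827GR (0.0156), and higher without HCC827 (0.0300) or HCC827ER (0.0301). With fry no list was called (smallest adjusted p = 0.162).

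Counted by size, 67 genes were at least 2-fold higher and 123 at least 2-fold lower in all 4 pairs, of 13769 genes, and 123 and 154 with a prior count of 0.5 in place of 2. At the prior count of 2, independent lists would share 20.7 and 28.1, and the highest of 10000 shuffles gave 38 and 51. Beside the genes above, the higher group held COL4A1, a basement membrane collagen (3.30 ± 1.33), and NUPR1, a stress-induced chromatin protein (4.14 ± 1.69), and the lower group held EGF and HES1, a Notch target (-2.08 ± 0.64). In both pairs of PC-9, 426 genes were higher and 538 lower, and in both of HCC827, 669 and 718, where the shared parental library alone gave 94.8 and 52.6, and 109.8 and 71.7, in simulation at an assumed dispersion of 0.05, and 1573.5 and 1248.4, and 1625.4 and 1299.2, at the 0.416 estimated between derived lines. At 0.416 the simulated pairs shared more genes than changed in all in PC-9ER (670 higher, 930 lower) or HCC827GR (957 and 1145). That setting is thus too wide for these pairs. The single parental libraries cannot be split and their own spread is not known, so how much of this sharing comes from them stays open. Over 3 pairs the counts were 118 and 168 without PC-9GR, 324 and 379 without PC-9ER, 159 and 194 without HCC827GR, and 92 and 194 without HCC827ER.

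Across genes, the log2 ratios of pairs with the same parent had a Pearson r of 0.29 (Spearman 0.34) for PC-9GR with PC-9ER and 0.50 (0.35) for HCC827GR with HCC827ER. In simulated unchanged lines the shared parental library alone gave an r of about 0.50 at each noise level, so r does not gauge agreement here. The covariances, 0.526 and 0.737, were above the 0.129 and 0.133 simulated at a dispersion of 0.05. They were below the 0.965 and 0.994 simulated at 0.416, the dispersion estimated between derived lines, which is too wide for these pairs. The spread of the parental libraries is not known, so agreement beyond the shared library stays open. Between parents, which share no library, r was 0.25 (Spearman 0.13) for the GR pairs and 0.18 (0.23) for the ER pairs. It was 0.22 (0.21) for PC-9GR with HCC827ER and 0.11 (0.04) for PC-9ER with HCC827GR. Both ER lines are in the second table and both parents in the first, so the ER pairs can share a difference of the tables.

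Within PC-9, both derived lines had more AKR1C transcripts, the 3 neighbouring enzymes AKR1C1 (7.78 CPM in PC-9, 1569 in PC-9GR and 129 in PC-9ER), AKR1C2 (63.9, 4742 and 2489) and AKR1C3 (26.0, 1554 and 367). VIM (7.25 ± 1.80), LRP3, the secreted protein GLIPR1 (5.11 ± 1.14), the matrix metalloproteinase MMP24 (4.93 ± 1.28) and the membrane protein PDZK1IP1 (0.515, 13.97 and 26.7 CPM) were also higher. Lower were the telomerase subunit TERT (72.0, 1.56 and 3.42 CPM), the mucosal defence protein DMBT1 (111, 0.168 and 3.30 CPM), MUC5B, the neurotensin receptor NTSR1 (59.4, 0 and 2.74 CPM), NWD1, TMPRSS4, CAPN8 and TH. EGFR was at -1.54 ± 0.77, YAP1 at -1.21 ± 0.69, WWTR1 at 0.48 ± 1.03 and MET at 0.32 ± 0.92.

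Of the lists in PC-9, MAPK output (22 of 22 members lower, adjusted p = 4.60e-10), epithelial genes (28 of 30, 2.87e-07), sterol and lipid synthesis (26 of 32, 2.91e-05), integrins and matrix (24 of 32, 5.93e-05), endothelial markers (4 of 5, 0.0409) and the list of trefoil factors and mucins (8 of 13, none a trefoil factor, 0.0479) fell. NRF2 targets (25 of 28 higher, 2.45e-06), mesenchymal genes (19 of 26, 0.000663), proliferation genes (26 of 32, 0.0195) and TGF-beta targets (17 of 25, 0.0479) rose. The smallest p for any of them was adjusted p = 0.717 with an estimated correlation. Without the library labelled PC-9GR, 7 lists were called, MAPK output (2.49e-21), sterol and lipid synthesis (5.58e-13), mesenchymal, trefoil and mucin (0.000321 each), integrin and matrix (0.00158), squamous and basal genes (higher, 0.0176) and proliferation (0.0191), and the epithelial, NRF2, endothelial and TGF-beta lists were not. With an estimated correlation none was called (smallest adjusted p = 0.872).

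No gene passed edgeR for PC-9 derived lines vs PC-9 (130 at the unadjusted threshold), DESeq2 called 86 higher and 6 lower, and limma-voom called 0 (194 unadjusted). Leaving out PC-9ER gave 999 genes and leaving out PC-9GR gave 2, MUC5B (-8.86 ± 1.76, adjusted p = 0.00674) and SPRY4 (-6.16 ± 1.35, adjusted p = 0.0333), both lower in PC-9ER. In these fits 1 derived library stands against 1 parental library and is assumed to vary as the HCC827 lines do. In the test of PC-9, NF-kB genes had a median of -0.30, a mean of 0.09 and a test direction of lower.

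Within HCC827, 8 genes each way were named by size, and none passed the test. The guanine exchange factor DOCK8 was at 0.0658, 13.4 and 24.6 CPM in HCC827, HCC827GR and HCC827ER, BCL2, which blocks apoptosis, at 0.132, 15.0 and 12.99, the heparan sulfate proteoglycan GPC4 at 0.0658, 19.6 and 14.7, and ALDH1A1, an aldehyde dehydrogenase, at 2.24, 173 and 847. TENM3, a cell adhesion teneurin (0, 17.4 and 9.27), SERPINF1, an inhibitor of vessel growth (0.132, 14.2 and 26.3), ZSWIM5 (0.395, 26.0 and 24.9) and MRAS were also higher. Lower were the secreted protease KLK6 (71.2, 0 and 0.421), the adhesion receptor ADGRF1 (27.0, 0 and 0.281), FGFBP1, which releases stored fibroblast growth factors (17.3, 0 and 0.211), the epithelial serpin SERPINB5 (14.4, 0.185 and 0.0702), and PCSK1N, UTP14C, KRT81 and POF1B (4.34 to 9.68 CPM in HCC827 and 0 counts in both derived lines). EGFR was at -2.46 ± 0.77, MET at -1.11 ± 0.88, YAP1 at -0.60 ± 0.70 and WWTR1 at -0.36 ± 1.00.

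The lists that fell in HCC827 were epithelial genes (30 of 30 lower, adjusted p = 3.18e-07), proliferation genes (30 of 32, 1.02e-06), MAPK output (20 of 22, 1.07e-05), the ERBB family (11 of 14, 0.000236), trefoil factors and mucins (11 of 13, none a trefoil factor, 0.000278), alveolar and airway genes (11 of 14, 0.00963) and sterol and lipid synthesis (26 of 32, 0.0179). NF-kB and inflammation genes rose (24 of 31 higher, 0.000569), with a median of 1.86 in HCC827ER and of 0.02 in HCC827GR, so the rise rests on 1 library. The smallest was adjusted p = 0.783 with an estimated correlation, and the count was 8 without PC-9GR. Proliferation genes were 2-fold or more lower in HCC827ER for 30 of 32 members (median -1.74), against a median of -0.11 in HCC827GR: the proliferation marker MKI67 was at 20.4 CPM in HCC827ER and at 340 to 527 CPM in the other 5 libraries. NT5E (-4.05 ± 0.62) passed adjusted over the list of YAP and TAZ targets alone (adjusted p = 0.0138). Leukocyte markers had a median of 0.03, a mean of -0.11 and a test direction of higher.

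No gene passed edgeR for HCC827 derived lines vs HCC827 (196 at the unadjusted threshold), DESeq2 called 28 higher and 14 lower, and limma-voom called 0 (178 unadjusted). The edgeR test takes its spread from the derived lines of both parents, so genes that differ between PC-9GR and PC-9ER get wide standard errors. KLK6, at 0 CPM in PC-9GR and 391 in PC-9ER, was at -8.39 ± 4.12, and at -8.41 ± 1.06 without PC-9GR. A missing call therefore does not show that the HCC827 lines disagree. Leaving out either PC-9GR or PC-9ER gave 159 genes, since the spread then comes from the HCC827 lines alone in both fits.

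The region around EGFR differed between the resistant lines. In HCC827GR all 10 measured neighbours within 1 Mb were lower, with a median log2 ratio of -2.42, beside -3.16 for EGFR, and SEC61G, a subunit of the protein translocation channel next to EGFR, was at 1851 CPM in HCC827 and at 115 CPM in HCC827GR. In HCC827ER the neighbours had a median of -0.22, beside -2.0 for EGFR, and SEC61G was at 1924 CPM. In PC-9ER the neighbours had a median of -0.10, beside -1.35 for EGFR, and in the library labelled PC-9GR -1.45, beside -1.77. HCC827GR had 37 windows of 9 genes past 1.5 (at most 5 in shuffled gene orders), HCC827ER 72 (35), PC-9ER 0 (2) and PC-9GR 525 (109). These included chromosome 17, 36601572 to 39402523, in HCC827GR (28 genes, median 1.59), and 37406874 to 38921770 in HCC827ER (21 genes, 1.55).

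**Figure D5:**
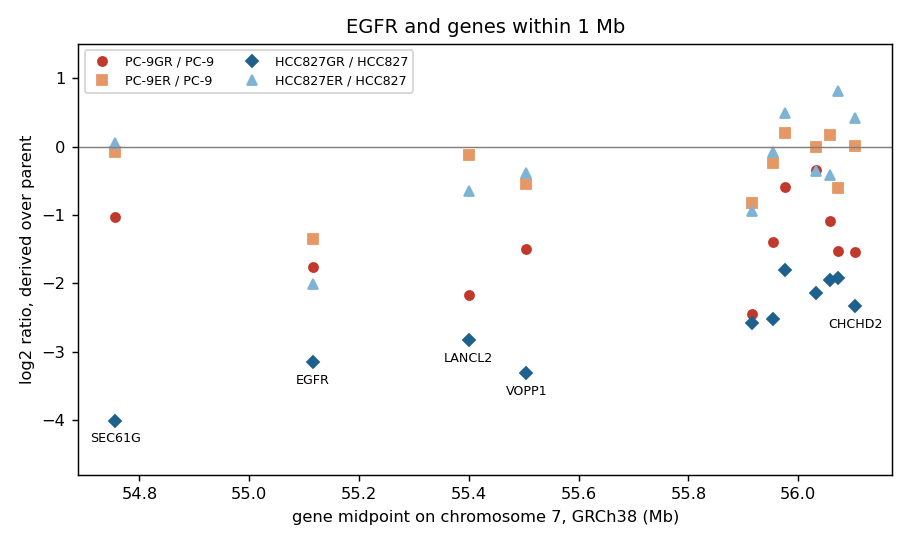
Log2 ratio to the parent against position on chromosome 7 (GRCh38, megabases) for EGFR and its neighbours within 1 Mb, 1 point per gene and derived line. In HCC827GR the neighbours have a median of -2.42 and in HCC827ER of -0.22.

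Setting the change in HCC827 against that in PC-9 put opposite movements at the top of the list. DOCK8 (10.93 ± 2.11), the extracellular matrix protein FBLN1 (7.07 ± 1.45) and BCL2 (8.29 ± 1.82) were lower in both PC-9 derived lines and higher in both HCC827 derived lines: FBLN1 was at 297, 77.6, 52.1, 0.329, 15.3 and 4.42 CPM. The collagen COL4A6 (-5.58 ± 1.10) and AREG, the EGFR ligand amphiregulin (-6.01 ± 1.36), went the other way, AREG at 3.09, 28.3, 9.13, 146, 10.9 and 16.5 CPM. COL12A1, a fibril-associated collagen (6.58 ± 1.53), and ANKRD1, a YAP target (4.68 ± 1.12), were higher in HCC827 lines, and INHBB, an activin subunit (-5.05 ± 1.01), the tubulin TUBB6 (-3.66 ± 0.95) and NT5E (-3.40 ± 0.91) gave negative differences. The fixed genes gave -0.92 ± 1.14 for EGFR, -1.43 ± 1.30 for MET, 0.61 ± 1.00 for YAP1 and -0.84 ± 1.43 for WWTR1.

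Among the lists, the change of proliferation genes differed between the parents (adjusted p = 1.05e-08; HCC827 change minus PC-9 change negative for all 32 members, median -1.50), and so did that of NF-kB and inflammation genes (adjusted p = 0.0121; positive for 23 of 31, median 1.26). Neither call held with an estimated correlation (smallest adjusted p = 0.761), and the NF-kB call was lost without HCC827ER (adjusted p = 0.790). For proliferation most of it came from HCC827ER, with a median of -1.74 against -0.11 in HCC827GR, 0.38 in PC-9GR and 0.44 in PC-9ER (adjusted p = 0.0247 without HCC827ER). When 1 library was left out the number of lists called was 8 without PC-9GR, 9 without PC-9ER and 4 without HCC827GR or HCC827ER, and the epithelial list was called in opposite directions, lower in HCC827 without PC-9GR (adjusted p = 1.46e-06) and higher without PC-9ER (1.57e-05). Median, mean and test direction differed in sign for epithelial (-0.0022, 0.36, higher), histone (0.59, -0.07, higher), squamous (0.04, 0.42, lower), glycolysis (0.03, -0.0040, higher) and stress response genes (-0.11, 0.08, higher), none of them called.

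No gene passed edgeR for the difference of the resistant-parental change between HCC827 and PC-9 (smallest adjusted p = 1.00; 118 at the unadjusted threshold), DESeq2 called 7 higher and 18 lower, and limma-voom called 0 (75 unadjusted). Without PC-9ER 506 genes were called, and without PC-9GR 12. In both fits the change in PC-9 is that of 1 derived against 1 parental library and the spread comes from the HCC827 derived lines alone, so these counts support no single gene.

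The ER lines had more transcripts of epithelial genes than the GR lines of the same parent, in a comparison that cannot be separated from the 2 tables, and no gene named here by size passed the test. CDH3, P-cadherin, was at 0.112 CPM in PC-9GR, 268 in PC-9ER, 1.61 in HCC827GR and 135 in HCC827ER, and RAB25, an epithelial trafficking protein, at 0.0559, 63.6, 0 and 8.36 CPM. LCN2, an iron-scavenging acute phase protein, was at 13.1, 974, 7.97 and 3268 CPM, SAA1, serum amyloid A, at 0.950, 61.6, 10.6 and 901, and the protease TMPRSS13 at 0, 54.4, 0.0618 and 9.13. IQGAP2, a scaffold of the cytoskeleton (16.5, 0.168, 19.6 and 0.351 CPM), the fatty acid elongase ELOVL2, PNMA8A, the kinase LRRK2 and SAMD5 were higher in the GR lines. WWTR1 (-1.57 ± 0.52) and MET (-1.18 ± 0.64) were lower and EGFR (0.74 ± 0.54) higher in the ER line of both parents, and YAP1 (-0.30 ± 0.53) was higher in PC-9ER and lower in HCC827ER than in the GR line.

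The lists of ER against GR were tested after the data had been seen. Epithelial genes (29 of 30 higher in ER, adjusted p = 3.54e-16), antigen presentation (18 of 20, 5.13e-05), NF-kB and inflammation genes (26 of 31, 0.000141) and squamous and basal genes (13 of 15, 0.00495) rose, and proliferation (30 of 32 lower, 9.55e-05) and MAPK output (17 of 22, 0.00962) fell. The smallest was adjusted p = 0.804 with an estimated correlation. The median fall of proliferation genes was seen in HCC827 and not in PC-9. With counts under 3 raised to 3, their medians against the parent were 0.39 in PC-9GR, 0.44 in PC-9ER, -0.11 in HCC827GR and -1.75 in HCC827ER. Over all lists 33 entries passed adjusted over the list alone, 10 of them epithelial, with ERBB3 counted in more than 1 list. Epithelial ones included RAB25 (9.75 ± 0.99, adjusted p = 0.00465), the transcription factor EHF (5.69 ± 0.87) and the receptor ERBB3 (3.44 ± 0.48, adjusted p = 0.0110 each). Among squamous genes the keratin KRT17 passed (6.17 ± 1.53). The largest folds were those of the cancer-testis antigens MAGEA3 (14.48 ± 1.04) and MAGEA4 (14.14 ± 1.22). Both had 0 counts in PC-9GR, and 346 and 273 CPM in PC-9ER. The median of the cancer-testis list against the parent was -6.78 in PC-9GR and -0.01 to 0.03 in the other derived lines. Without PC-9GR, with 1 GR library left, 10 lists were called: trefoil factors and mucins (higher, 0.000606), glycolysis and hypoxia (higher, 0.00219), the Hippo list (lower, 0.00683), NRF2 targets (higher, 0.00739), YAP and TAZ targets (lower, 0.0119) and interferon-stimulated genes (higher, 0.0368) were added, and squamous genes and MAPK output were no longer called. With an estimated correlation none of them was called (adjusted p = 0.784 for each of the 10). Without HCC827GR 10 lists were called as well.

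No gene passed edgeR for ER vs GR lines (smallest adjusted p = 0.419; 931 at the unadjusted threshold, 675 expected by chance), DESeq2 called 201 higher and 139 lower, and limma-voom called 0 (1192 unadjusted). Without PC-9GR 54 genes were called and without HCC827GR 1291. In these fits the GR side is 1 library and the spread, with 1 residual degree of freedom, is that between the changes in the ER lines of both parents, so these counts support no single gene.

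In single pairs, which have no test, ALDH1A1 was at 7181 CPM in the library labelled PC-9GR (128488 counts against 1 in PC-9, a ratio between 22519 and 4955900). CPLX2, which acts in vesicle release, was at least 8124-fold higher there and the kinase SIK1B at least 1960-fold, whereas MAL was at least 4317-fold lower and LCP1 had 1 count against 16048. In PC-9ER the sulfotransferase SULT1A4 was at least 92.6-fold higher, NLRP7 had 259 counts against 2 (a ratio between 34.7 and 1052), and PDZK1IP1 had a log2 ratio of 5.40, while MUC5B had 1 count against 517, and SPRY4 (-6.03) and TMPRSS4 (-5.86) were lower. In HCC827GR the membrane peptidase MME was at least 217-fold and TENM3 at least 87.9-fold higher, and DOCK11 had 337 counts against 1 (a ratio between 56.4 and 12529). KLK6 was at least 384-fold and SCEL, an envelope protein of squamous cells, at least 275-fold lower in HCC827GR, and PROM2, a membrane protein of epithelial protrusions, had a log2 ratio of -8.42. In HCC827ER the acute phase protein CRP was at least 838-fold higher, AKR1C2 (log2 ratio 9.27) and ALDH1A1 (8.49) were higher, and EGR1 (-7.40), KLK6 (-7.04) and the lung lineage factor NKX2-1 (at least 69.1-fold) were lower. Reads of SULT1A4 and SIK1B can come from near-identical copies.

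By size, 2814 genes were 2-fold or more higher and 2605 lower in PC-9GR, 670 and 930 in PC-9ER, 957 and 1145 in HCC827GR, and 2251 and 2417 in HCC827ER, of 12273 to 13002 genes per pair. These counts have no replicate behind them.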

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

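All of the tests of explanations in this part, and the surveys of chromosome regions, were chosen only after the result was seen. Of 62 values compared across the 4 pairs or resistant lines, 9 had 1 library far from the other 3 by Dixon's 95% criterion. For independent and unselected values chance gives about 1 in 20. These values overlap, and some genes were chosen by size over the same pairs, so that rate is no measure of chance here.

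The library labelled PC-9GR accounted for 7 of these 9. It had 323 genes silent in PC-9 and expressed in it (3 to 36 in the other pairs) and 254 expressed in PC-9 and silent in it (3 to 43). Its median log2 ratio was -6.78 for cancer-testis antigens (-0.01 to 0.03 in the others), -7.17 for endothelial markers (-0.80 to -0.06) and 1.60 for drug handling (0 to 0.17). MSRB3 was at 5.62 (1.61 to 2.14) and KCNJ18 at -6.40 (-3.26 to -3.19). KCNJ18 had 0 counts in PC-9GR, HCC827GR and HCC827ER, so these ratios are set by the parental level, 10.1 CPM in PC-9 and 0.987 in HCC827. Its gap is therefore not particular to the library labelled PC-9GR. Among genes that the comparisons did not use because the second table does not list them, 45 were at 5 CPM or more in this library with at most 3 counts in both parental libraries, led by GABRA5, a GABA receptor subunit (109 CPM), the neurotrophin receptor NTRK3 (61.0), the BMP antagonist GREM1 (58.7) and the axon guidance ligand SLIT3 (52.1).

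The pattern is that the library labelled PC-9GR stands apart from PC-9. A mixture of PC-9 cells with other cells is argued against, since 42 genes at 100 CPM or more in PC-9 had at most 3 counts in it, among them LCP1, ANO1, MAL and KLK6, all of them seen in PC-9ER. A mislabelled sample, or a line that does not descend from the PC-9 stock sequenced here, and change acquired by PC-9 cells during selection, the biological explanation that the design names, cannot be told apart. The Spearman correlation of 0.773 with PC-9 is the pattern itself and tests neither, and that with HCC827GR, 0.828, is below those of the other derived lines with their parents (0.888 to 0.96). Also, 4 runs of neighbouring genes silent in PC-9 were expressed, among them DYNLT3, SRPX, RPGR and MID1IP1 (chromosome X, 37836757 to 38806537), at 0 counts in PC-9 and PC-9ER, but RNA does not show whether such a segment is absent or silenced. No other cell line was compared, and all values for this library rest on 1 culture.

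The second pattern is the low EGFR in both HCC827 derived lines. In HCC827GR the 10 neighbours of EGFR had a median log2 ratio of -2.42 and ranged from -4.01 (SEC61G) to -1.80, which lower copy number of the region may account for, and the values it needs are there. Library scaling is argued against, since the neighbours lay 2.42 below the median of all genes. In HCC827ER lower copy number of the whole region is argued against: the neighbours had a median of -0.22, the lowest at -0.94, and EGFR was at -2.0. What lowered EGFR in HCC827ER and in PC-9ER was not tested, and no DNA was measured.

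The third pattern is the low proliferation list in HCC827ER. A difference between the 2 tables is argued against, since the list had a median of 0.44 in PC-9ER, which is in the same table, and so is scaling, which moves all genes of a library alike, since the list lay 1.74 below the median of all genes. Slower growth of this line, with 30 of 32 genes at least 2-fold lower, cannot be told apart from the state of this culture or its RNA, because HCC827ER has 1 library. That library also had the highest share of ribosomal protein counts, 16.1% against 7.38% to 7.62% in the other resistant lines.

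The change differed between the parents for the proliferation list (adjusted p = 1.05e-08) and for NF-kB and inflammation genes (adjusted p = 0.0121), with medians of HCC827 minus PC-9 of -1.50 and 1.26. Neither call held with an estimated correlation (smallest adjusted p = 0.761), and that of NF-kB genes was lost without HCC827ER (adjusted p = 0.790). DOCK8 (10.93), BCL2 (8.29), FBLN1 (7.07), COL4A6 (-5.58) and AREG (-6.01) moved in opposite directions in both pairs of each parent, and none passed the test of the difference (adjusted p = 1.00 each). The MAPK output list was lowest in PC-9ER, with a median of -2.15 against -1.18 to -0.99 in the other 3 pairs. The second table alone listed 1 gene at 5 CPM or more in HCC827ER, the histone gene H2AC19, at 24.1 CPM.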

How the results depend on the processing

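The list, pair and first-table alternatives named here with leaving out a library were chosen after the data had been seen, as were the fits with genes absent from 1 table set to 0. With edgeR, 0 genes passed in all 5 comparisons under the size factors of DESeq2, no filter, the stricter filter and absent genes at 0, with 342, 130, 196, 118 and 931 genes at an unadjusted threshold of 0.05 in the main settings, and limma-voom called 0 as well. DESeq2 called 34 genes for resistant against parental lines, 92 in PC-9, 42 in HCC827, 25 for the difference and 340 for ER against GR, and the cause was not tested. The size factors moved the median of all genes by at most 0.011. Over 140 results on named genes, 1582 of 1713 values under alternatives kept direction and side of the threshold, 114 passed it and 17 turned direction. No gene had passed in the main settings, so no call could be lost and this count is no measure of stability. Over 56 list results, 367 of 467 stayed, 32 passed, 15 lost the call and 53 turned direction, and all 48 values of genes in single pairs stayed. The depth leaves genes below about 0.2 CPM unmeasured, and 1 library per line leaves the spread of a line unmeasured.

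The direction of WWTR1 turned with limma-voom (-0.17) and with no block for line of origin (-0.044), and that of MET with the first table only (0.068). For both parents, leaving out PC-9 or HCC827 leaves the change in the other parent alone. Fewer libraries set the spread by construction when 1 is left out. The count of genes then ranged from 0 (without HCC827) to 999 (without PC-9ER) in PC-9, from 0 to 159 (without PC-9GR or PC-9ER) in HCC827, from 0 to 506 (without PC-9ER) for the difference and from 0 to 1291 (without HCC827GR) for ER against GR, and was 0 throughout for both parents. For both parents WWTR1 ranged from -0.68 (without PC-9GR) to 0.47 (without HCC827), MET from -1.11 (without PC-9) to 0.31 (without HCC827), AMOT from -3.06 to 3.91, RRM2 from -1.44 to 0.017, VCAM1 from -0.87 to 10.42 and BCL2A1 from -0.44 to 5.72. In PC-9, WWTR1 ranged from -1.06 to 1.20 and MET from -0.068 to 0.61. For the difference WWTR1 ranged from -1.56 to 0.69, and for ER against GR YAP1 ranged from -0.97 to 0.48. Some genes at 0 in the remaining libraries had no value.

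Genes 2-fold changed in all 4 pairs numbered 123 higher and 154 lower with a prior count of 0.5. With 4-fold they were 8 higher and 16 lower, and single pairs had 1385 higher and 1296 lower (PC-9GR), 147 and 211 (PC-9ER), 352 and 495 (HCC827GR), and 673 and 631 (HCC827ER). With at least 5 CPM, 413 genes were 2-fold higher in PC-9ER. Over 3 pairs the shared genes numbered 92 (without HCC827ER) to 324 (without PC-9ER) higher and 168 (without PC-9GR) to 379 (without PC-9ER) lower, and fewer pairs give more by construction. The correlation was 0.270 for PC-9GR with PC-9ER, 0.145 for PC-9ER with HCC827ER and 0.528 for HCC827GR with HCC827ER with a prior count of 0.5, and 0.274 for PC-9GR with HCC827GR and 0.203 for PC-9ER with HCC827ER at 5 CPM or more.

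With an estimated correlation 0 lists were called for both parents and 0 for the difference. Cancer-testis antigens turned direction with the stricter filter, at adjusted p = 0.890 for both parents and 0.571 for the difference. With the first table only, adjusted p was 0.209 for antigen presentation, 0.772 for bypass receptors, 0.664 for cancer-testis antigens, 0.623 for glycolysis, 0.248 for NF-kB genes and 0.278 for proliferation, all turned in direction. With 1 library left out, adjusted p for both parents ranged from 0.0393 to 0.941 for antigen presentation, from 0.259 to 0.928 for bypass receptors, from 0.425 to 0.978 for cancer-testis antigens, from 0.150 to 0.944 for glycolysis, from 0.469 to 0.933 for leukocyte markers, from 0.163 to 0.978 for interferon genes, from 0.0580 to 0.919 for neuroendocrine markers, from 0.000740 to 0.900 for NF-kB genes, from 1.27e-06 to 0.106 for proliferation, from 0.459 to 0.990 for the stress response and from 0.427 to 0.880 for YAP and TAZ targets. Each of these turned direction at least once. Over every alternative, adjusted p ranged from 0.0382 to 0.862 for the Hippo list, from 0.00806 to 0.933 for squamous genes, and from 0.000270 to 0.652 for the ERBB family.

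For the difference, 4 (without HCC827GR or HCC827ER) to 9 lists (without PC-9ER) were called with 1 library left out. Adjusted p ranged from 0.00646 to 0.947 for antigen presentation, from 0.145 to 0.582 for bypass receptors, from 0.418 to 0.888 for cancer-testis antigens, from 0.0171 to 0.914 for drug handling, from 1.46e-06 (opposite direction, without PC-9GR) to 0.390 for epithelial genes, from 0.0803 to 0.978 for glycolysis, from 0.376 to 0.978 for the Hippo list, from 0.214 to 0.771 for histones, from 0.00436 to 0.896 for NRF2 targets, from 0.000153 to 0.971 for squamous genes, from 0.00475 to 0.806 for sterol synthesis, from 0.344 to 0.945 for the stress response and from 0.109 to 0.863 for trefoil factors and mucins. The causes of these changes were not tested. Not fitted were PC-9 without its parental library, HCC827 without its own, the difference without either, and the first table only for all but resistant against parental lines.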

Other observations

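The comparisons and gene choices in this part were made after the data had been seen, and its values are given without a test. Regulators of apoptosis that EGFR inhibitors act through differed little in 1 case and more in another. BCL2L11, which encodes the death-promoting protein BIM, was at 39.8, 48.2, 41.9, 45.2, 42.3 and 31.2 CPM in PC-9, PC-9GR, PC-9ER, HCC827, HCC827GR and HCC827ER. BCL2L1, which encodes the survival protein BCL-XL, was at 208, 305, 75.9, 289, 283 and 495 CPM in the same order. Some keratins of basal epithelium were highest in PC-9ER among the PC-9 libraries, with KRT5 at 5.72, 0 and 94.2 CPM and KRT6A at 0.916, 0 and 17.6 CPM in PC-9, PC-9GR and PC-9ER, and KRT17 at 1.37, 0.0559 and 19.4 CPM, but KRT15, at 28.7, 0.838 and 7.73 CPM, was lower in both derived lines. In HCC827ER, B2M, the invariant chain of class I antigen presentation, was at 1876 CPM against 343 in HCC827, the matrix protein SPP1 at 6266 against 81.7, and the glutathione transferase GSTA1 at 272 against 1.51.

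Both HCC827 derived lines shared segments of altered expression. On chromosome 17, log2 ratios in HCC827GR and HCC827ER were 2.57 and 2.46 for DUSP14, a phosphatase, 3.05 and 2.68 for the mitochondrial ribosomal gene MRPL45, and 3.29 and 1.76 for MLLT6, within segments of 28 genes (median 1.59) and 21 genes (median 1.55). On chromosome X, 15 neighbouring genes were lower in HCC827GR (80670854 to 100929433, median -1.28) and 15 in HCC827ER (77968874 to 100732123, median -1.76). They included DIAPH2, a formin (-6.80 and -2.85), and APOOL, a mitochondrial protein (-5.25 and -2.88). Both lines are set against the same HCC827 library, so whatever is particular to that library, noise included, is shared between these values. A change of that parental culture cannot be told apart here from one of the derived lines.

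In the library labelled PC-9GR, genes in neighbouring clusters were silent that PC-9 expressed: the kallikreins KLK5, KLK6, KLK7 and KLK8 on chromosome 19 (50943303 to 51002711) and 9 genes on chromosome X (152166234 to 152769747), GABRA3 and members of the MAGEA and CSAG families. These values rest on this library alone.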
